A study of Rattus norvegicus with 35 samples.

How the data were processed

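Liver RNA of 35 rats in 6 groups was measured on single-colour Affymetrix arrays with biotin-labelled total RNA, per the labels. The groups were control sham (n = 5), control hemorrhage and resuscitation (n = 6), ligated sham (n = 5), ligated hemorrhage and resuscitation (n = 6), ligated simvastatin sham (n = 5) and ligated simvastatin hemorrhage and resuscitation (n = 8). Groups were read from the sample labels, and replicate numbers follow the order of the samples within a group. Whether ligated rats without simvastatin received vehicle is not stated in the labels, so the drug comparisons may contrast simvastatin with vehicle gavage or with no gavage.

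The values were used as the authors deposited them, as normalized log2 signals per probe set, and the normalization method is not given in the sources used here. The log2 scale was read from the values, which run from 1.51 to 13.79 with array medians between 3.97 and 4.29. No image or probe-level file was used here. The highest correlation between 2 arrays was 0.992, and 0 pairs of arrays were identical. Depth in the sense of reads does not apply to arrays, and precision rests on the 5 to 8 arrays per group.

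Of the probe sets 19068 (61.2%) carried 1 gene symbol, 572 carried several, and 11498 (36.9%) had no gene listed in the table used here. The tests used probe sets with 1 symbol, and for each of 13438 genes the probe set with the highest mean over all arrays, since 3986 genes had several. A gene was taken as not above background in a group when its mean there was not above the mean, over the arrays of that group, of the brightest nonspecific probe (2.71 to 5.16 on single arrays), and its fold then counts as a bound against that mean. Probe sets with several symbols or none were left out of the gene tests and tested as a set apart. Genes of families with similar sequences, such as Cyp2c and Cyp3a, may share probes, so a value for 1 member can include signal of its relatives.

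Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group over all 35 arrays was fitted with lmFit and moderated with eBayes. The 8 comparisons were ligated sham against control sham, H/R against sham in control, ligated and simvastatin-treated rats, simvastatin against no simvastatin in sham and in H/R rats, the difference of the H/R effects of ligated and control rats, and the difference of the H/R effects of ligated rats with and without simvastatin. The p-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were counted as past the threshold.

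Gene groups were 25 lists written from general knowledge before the data were examined, with 521 entries, of which 457 matched a gene on the array. They covered hepatocyte function, cholangiocyte and ductular markers, stellate cells and matrix, sterol synthesis, bile acids, immediate early genes, hypoxia, cytokines with chemokines and adhesion molecules, acute phase proteins, heat shock, the unfolded protein and integrated stress response, and oxidative stress with NRF2 targets. The others covered endothelial, macrophage, neutrophil, lymphocyte and red cell markers, the cell cycle, p53 targets, cytochrome P450, fatty acid oxidation, lipogenesis, gluconeogenesis with glucocorticoid response, and the circadian clock. The results of 1 further list and of its members other than Klf2 and Nos3, some of which passed, were part of the adjustment and are not reported here. Each list was tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The median log2 change of a list, its mean and the direction of the test differed in sign in 15 of 200 list tests, and none of these 15 passed.

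Genes were named by a rule fixed beforehand. It took the 10 largest rises and the 10 largest falls among genes past the threshold in each comparison, leaving out uncharacterised loci, olfactory and vomeronasal receptors and small RNA genes. Where fewer than 5 genes passed it added the 5 of smallest p. It also took up to 4 members of each list with the smallest p, and Klf2 and Nos3 in the simvastatin comparisons whatever their p.

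Alternatives fixed before the data were examined were a fit of the groups in the comparison only, eBayes with trend and robust options, array weights, only genes with a mean above the 30th percentile, quantile normalization of the deposited values again, centring each array on its median, the mean of all probe sets of a gene, and leaving out each array in turn. A further alternative took the last 2 digits of the number in the sample title, whose meaning is not stated, as a block for the 3 comparisons of sham and H/R arms within ligated rats. All control arrays share 1 ending that no untreated ligated array has, and ligated sham and simvastatin sham arrays share none. Ligation and simvastatin in sham rats are therefore confounded with this number and could not be blocked on it, and neither was simvastatin in H/R rats, where the arms share 1 ending. Alternatives chosen after seeing the data, on ligated arrays only, used the mean of the duct and matrix lists or the difference of the hybridisation controls BioD 5' and BioB 5' as a covariate. A last one left out the 2 arrays of largest residual spread.

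The steps were tested on simulated data with 50 changed genes at each of 4 sizes in every comparison. Genes changed by 1 log2 were recovered in 84% to 90% of cases in the 6 comparisons of 2 groups and in 72% and 66% in the 2 tests of a difference between effects. Genes changed by 0.5 log2 were recovered in 22% to 46% and in 10% and 16%. Between 2 and 13 of about 13225 unchanged genes passed. The simulated noise was independent between genes and had the same spread in every group. Correlated genes, batches and outlying arrays were therefore not represented, and these rates need not hold for the real arrays. Permutation tests on list means and control probes used all arrangements or 100000 resamples, and 100 regroupings of the same arrays were drawn for each comparison. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.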

Results

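Liver gene expression was measured on 35 single-colour arrays, 1 per liver sample, in 6 groups of rats. Control rats had either a sham procedure (control sham, n = 5) or hemorrhage followed by resuscitation, abbreviated H/R (control H/R, n = 6). Rats with secondary biliary cirrhosis, produced by ligating the common bile duct, were sampled 4 weeks after the ligation and had the sham procedure (ligated sham, n = 5) or H/R (ligated H/R, n = 6). In a further pair of ligated groups simvastatin, an inhibitor of HMG-CoA reductase, was given by gavage at 5 mg per kg once daily, starting 3 days before the experiment, with the last dose 1 h before it (simvastatin sham, n = 5, and simvastatin H/R, n = 8). The labels do not say whether the ligated rats without simvastatin received vehicle by gavage or nothing, and untreated means without simvastatin. The deposited values were normalized log2 signals with array medians between 3.97 and 4.29, and 13438 genes entered the tests. The comparisons, the tests, 25 gene lists, the rule for naming genes and most alternative settings were chosen before the data were examined. Array data carry no read depth, so precision is limited by the number of arrays in each group. The labels give a group and a number for each sample and nothing more on the animals, so the p-values measure the spread between these samples. Where the mean of the dimmer group lay at or under the mean of its brightest nonspecific probe, the fold is a bound and written as at least that fold. Errors of log2 differences are standard errors from the limma fit, and adjusted p-values are Benjamini-Hochberg values over all genes unless said otherwise.

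The series title names liver injury in cirrhotic rodents after H/R and its attenuation by simvastatin as the subject. Comparing ligated sham with control sham livers gave the state of the liver before either intervention. The lists of the biliary epithelium and of the fibrous matrix rose after ligation and held with an estimated correlation. The lists of lipogenesis, sterol synthesis, fatty acid oxidation and drug metabolism passed downward with the preset correlation only (adjusted p = 0.23, 0.41, 0.49 and 0.38 with an estimated correlation). Cd24, a surface protein of ductular cells, rose 41.2-fold (log2 5.36 ± 0.27, adjusted p = 2.7e-16), and Krt19, a keratin of the biliary epithelium, rose 28.1-fold (log2 4.81 ± 0.31, adjusted p = 3.4e-14). Loxl1, which crosslinks elastin fibres, rose at least 23.5-fold (log2 5.00 ± 0.44, adjusted p = 3.4e-11). Car3, a carbonic anhydrase abundant in male rat liver, fell 83.1-fold (log2 -6.38 ± 0.59, adjusted p = 1e-10), and Cyp2c11, the main male-specific cytochrome P450 of rat liver, fell 69.3-fold (log2 -6.12 ± 0.56, adjusted p = 9.4e-11). In all, 6401 of the 13438 genes passed an adjusted p of 0.05, 3394 higher and 3007 lower in ligated livers. Of these, 1524 rose and 660 fell at least 2-fold.

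By estimated log2 change the 10 largest rises were in Sncg, Itgb6, Dclk1, Map2, Msln, Tsx, Cd24, Tspan8, Dcdc2 and Sctr. All of them except Cd24 and Tspan8 were not above the nonspecific probes in control sham arrays. Their folds are bounds (at least 17.6-fold for Map2), so their order and their rank against measured rises such as that of Krt19 are not established. Sctr, the secretin receptor of bile duct cells, rose at least 25-fold and Sncg, a synuclein, at least 40.8-fold (log2 5.12 ± 0.39 and 6.30 ± 0.87, adjusted p = 2e-12 and 3.8e-07). Itgb6, an epithelial integrin subunit that activates TGF-beta, rose at least 23-fold (log2 6.08 ± 0.48, adjusted p = 3.5e-12), and Msln, the mesothelial protein mesothelin, rose at least 38-fold. By the same estimate the 10 largest falls were in Obp3, Car3, Cyp2c11, Slc22a8, Cxcl10, Gstp3, Il1a, Stac3, Cxcl9 and Lin7a. Slc22a8, Stac3 and Lin7a were not above the nonspecific probes in ligated sham arrays and fell at least 21.8-, 8.48- and 10.3-fold, so their ranks are not established. Obp3, a lipocalin of the family that binds odorants, fell 86.3-fold (log2 -6.43 ± 0.65, adjusted p = 7.8e-10). The chemokine gene Cxcl10 fell 23.5-fold and the cytokine gene Il1a 18.8-fold, with adjusted p = 1.9e-06 and 2e-06.

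Of the 20 measured cholangiocyte and ductular markers 16 rose and 0 fell (adjusted over the list alone, 17 rose and 1 fell), with a median log2 change of 3.80. The set test camera gave an adjusted p of 7.4e-14 and the list held with an estimated correlation (adjusted p = 0.029). Epcam, an epithelial adhesion molecule, rose 17-fold and Krt8 rose 5.94-fold. Among 27 genes of stellate cells, myofibroblasts and matrix 24 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 2.01 and an adjusted p of 4.7e-12, and this list also held with an estimated correlation (adjusted p = 0.029). Col5a2 and Col6a3, chains of fibrillar and microfibrillar collagens, rose 6.80- and 7.13-fold, and Vim, the intermediate filament vimentin, rose 11.5-fold. No other list held with an estimated correlation in this comparison. Mean log2 signals of the duct list were 5.29 ± 0.29 (SD, n = 5) in control sham and 8.49 ± 0.42 (SD, n = 5) in ligated sham arrays. Those of the matrix list were 6.02 ± 0.15 and 7.92 ± 0.24. The arrays of control and untreated ligated livers also differed in hybridisation controls, in the BioD minus BioB signal, which was 2.13 ± 0.11 (SD, 11 arrays) in controls and 2.55 ± 0.12 (SD, 11 arrays) in untreated ligated livers.

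Cell cycle genes rose in 16 of 25 cases (17 adjusted over the list alone) with 0 falls, a median of 0.99 and an adjusted p of 3.3e-04, against adjusted p = 0.49 with an estimated correlation. Mcm6, a DNA replication helicase subunit, rose 2.61-fold and Ccna2, cyclin A2, at least 2.22-fold. Of 16 Kupffer cell and macrophage markers 8 rose and 2 fell (8 and 3 adjusted over the list alone), with a median of 0.65 and an adjusted p of 0.050 that lay just under the threshold (adjusted p = 0.49 with an estimated correlation). Gpnmb, Lyz2 and C1qc, markers of phagocytes, rose 5.63-, 4.58- and 3.53-fold. The 15 endothelial markers had 6 rises, among them Vwf at no less than 2.10-fold, and 2 falls (7 and 2 adjusted over the list alone; adjusted p of the list 0.11).

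All 14 lipogenesis genes had negative changes and 12 of them fell (12 adjusted over the list alone), with a median of -1.62 and an adjusted p of 1e-05 (adjusted p = 0.23 with an estimated correlation). Fasn, fatty acid synthase, fell 4.70-fold and Elovl6, a fatty acid elongase, 6.21-fold. Sterol synthesis genes behaved similarly, with 16 of 21 lower and 0 higher (16 and 0 adjusted over the list alone), a median of -0.83 and an adjusted p of 1.7e-05 (adjusted p = 0.41 with an estimated correlation). Fdft1, squalene synthase, fell 2.71-fold. Of 19 genes of fatty acid oxidation and PPAR alpha targets 13 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.70 and an adjusted p of 3.2e-04 (adjusted p = 0.49 with an estimated correlation). Fabp1, the liver fatty acid binding protein, fell 4.90-fold and Fgf21, a fasting hormone, 7.16-fold. Among 15 genes of cytochrome P450 and drug metabolism 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -1.82 and an adjusted p of 3.3e-04 (adjusted p = 0.38 with an estimated correlation). Cyp3a9 fell 6.31-fold and Ugt2b1, a glucuronosyltransferase, 9.59-fold.

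The unfolded protein and integrated stress response list had 16 falls and 1 rise among 21 genes (18 and 1 adjusted over the list alone), with a median of -0.70 and an adjusted p of 2e-05 (adjusted p = 0.38 with an estimated correlation). Dnajb9, a chaperone of the endoplasmic reticulum, fell 2.51-fold and Asns, asparagine synthetase, 2.60-fold. Cytokine, chemokine and adhesion genes fell in 14 of 25 cases and rose in 2 (14 and 2 adjusted over the list alone), with a median of -1.10 and an adjusted p of 0.0015 (adjusted p = 0.49 with an estimated correlation). Il10, an anti-inflammatory cytokine, fell 5.21-fold, and Il1rn, the interleukin 1 receptor antagonist, 4.02-fold. For acute phase proteins 11 of 20 fell and 1 rose (11 and 2 adjusted over the list alone), at a median of -0.36 and an adjusted p of 0.0082 (adjusted p = 0.49 with an estimated correlation). Apcs, serum amyloid P, fell 3.02-fold. Bile acid genes fell in 11 of 22 cases and rose in 2 (12 and 2 adjusted over the list alone), with a median of -0.72 and an adjusted p of 0.026 (adjusted p = 0.49 with an estimated correlation). The 2 that rose were Abcc3, a basolateral efflux pump, at 6.40-fold or more (log2 3.07 ± 0.20, adjusted p = 4.4e-14), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 5.79-fold (log2 2.53 ± 0.41, adjusted p = 6e-06). Slc10a1, the sodium-dependent bile acid importer, fell 4.35-fold. Of 20 hepatocyte function genes 8 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.25 and an adjusted p of 0.026 (adjusted p = 0.52 with an estimated correlation). The urea cycle gene Otc fell 3.21-fold.

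The other lists did not pass in this comparison. Heat shock genes split into 2 rises and 6 falls of 14 (2 and 6 adjusted over the list alone), and their median of -0.26 and mean of 0.09 differed in sign (adjusted p = 0.24). Cryab, a small heat shock protein, rose at least 18.9-fold, and Hsph1 fell 2.56-fold. Oxidative stress and NRF2 targets had 4 rises and 8 falls of 18 (adjusted p of the list 0.16), with Gpx2, a glutathione peroxidase, at least 21.6-fold higher and Me1, malic enzyme, 4.51-fold lower. Clock genes had 6 rises and 3 falls of 15 (adjusted p of the list 0.28), among them Per2 at 6.85-fold higher or more and Hlf at 5.71-fold lower. The hypoxia list had 6 rises and 4 falls of 22 (adjusted p 0.47), with Ndrg1 6.35-fold higher, and immediate early genes 2 rises and 5 falls of 22 (adjusted p 0.18). Lymphocyte markers had 5 rises and 3 falls of 18 (adjusted p 0.50), p53 targets 1 rise and 3 falls of 13 (adjusted p 0.30), and gluconeogenesis and glucocorticoid genes 1 rise and 4 falls of 15 (adjusted p 0.16). Neutrophil markers had 0 of 9 past the threshold in limma and adjusted over the list alone (adjusted p of the list 0.84), and red cell markers had 1 fall of 8 (adjusted p 0.24).

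The balance of rises and falls after ligation depended on the scaling. With each array centred on its median, 1949 genes were higher and 7356 lower and the median change of all genes went from -0.043 to -0.423, and with the values quantile normalized again 2785 were higher and 3754 lower. No list past the threshold changed direction under either, but the bile acid list no longer passed under both, the cytokine list under centring, and the hepatocyte and acute phase lists under quantile normalization.

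**Figure D1:**
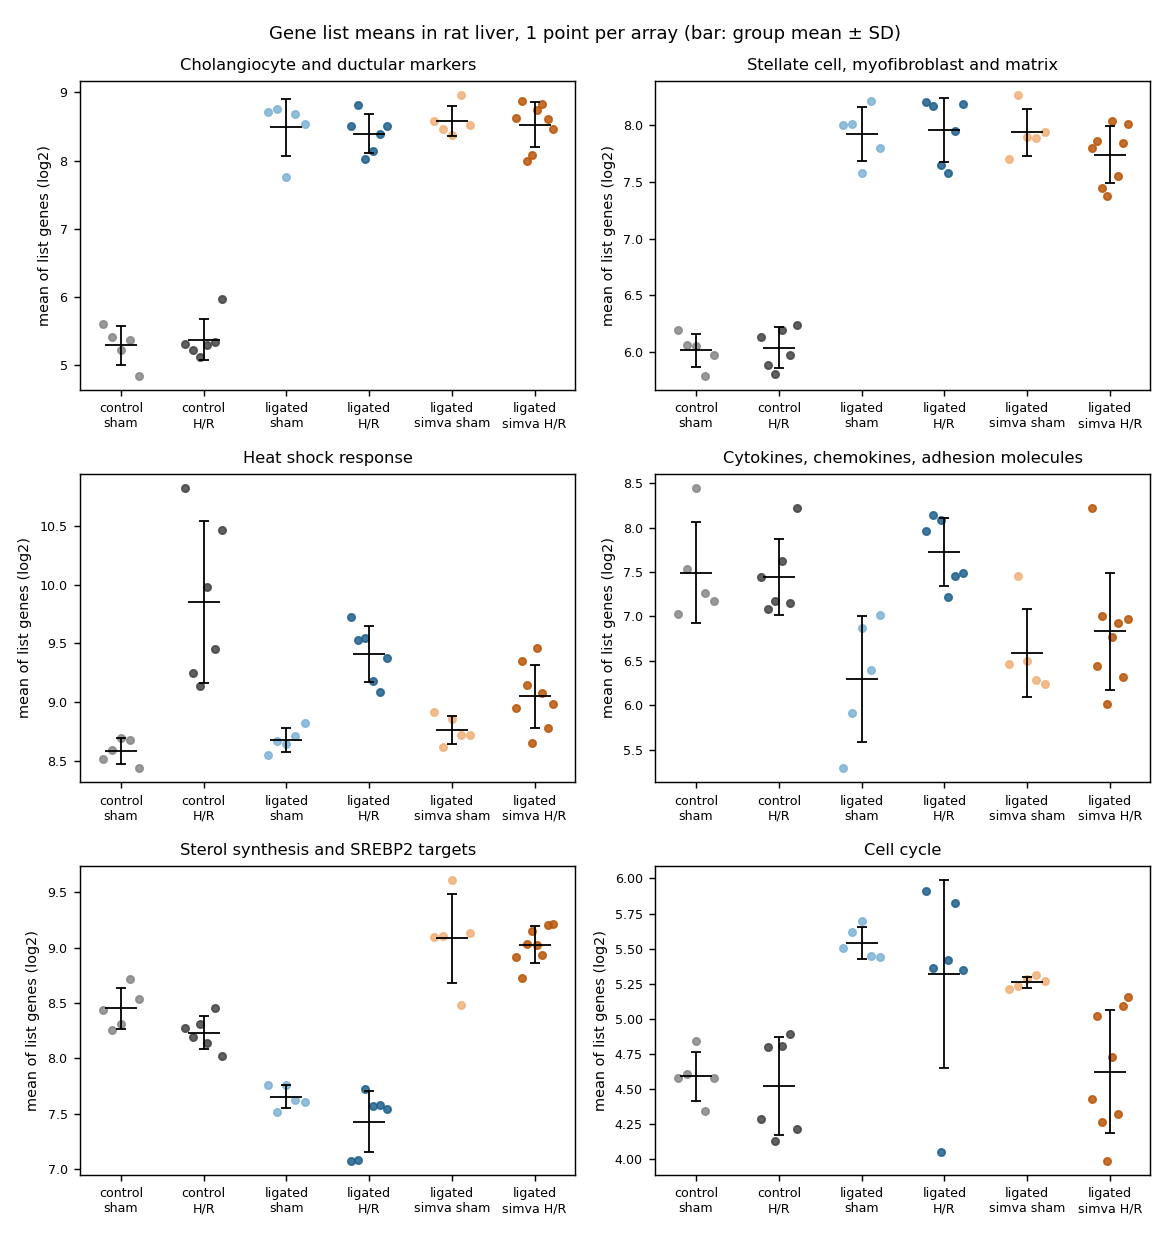
Mean log2 signal of 6 gene lists (vertical axes) in the 6 groups (horizontal axis); each point is 1 array, and the bar with whiskers is the group mean ± SD. The duct and matrix lists lie near 5.29 and 6.02 in control sham and near 8.49 and 7.92 in ligated sham arrays, heat shock genes are at 9.85 in control H/R against 8.58 in control sham, and the sterol list is at 9.08 and 9.03 in the simvastatin groups against 7.65 and 7.43 in the untreated ligated groups.

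H/R in livers without cirrhosis was examined by comparing control H/R with control sham rats. Heat shock genes rose as a group. Hspb1, a small heat shock protein, rose 19.6-fold (log2 4.30 ± 0.44, adjusted p = 3.2e-07), from 5.55 to 6.34 log2 in the 5 sham arrays to 8.55 to 11.89 in the 6 H/R arrays. Hspa1a, the inducible Hsp70, rose 9.64-fold (log2 3.27 ± 0.50, adjusted p = 0.00032), and its cochaperones Dnaja4 (5.67-fold, adjusted p = 3.2e-07), Dnajb1 (3.48-fold, adjusted p = 0.0041) and Bag3 (3.15-fold, adjusted p = 0.0041) rose with it. Phgdh, the enzyme that opens serine synthesis, fell 4.70-fold (log2 -2.23 ± 0.28, adjusted p = 9.9e-06), and Psat1, the next enzyme of that path, 2.38-fold (log2 -1.25 ± 0.24, adjusted p = 0.0052), while Psph, the last, did not pass (log2 -0.05 ± 0.18, adjusted p = 0.96). In all 115 genes passed, 49 higher and 66 lower, of which 23 rose and 18 fell at least 2-fold.

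Of the 14 heat shock genes all had positive changes, 8 rose over all genes and 12 adjusted over the list alone. Their median was 0.77, camera gave an adjusted p of 1.2e-22, and the list held with an estimated correlation (adjusted p = 0.017). Hspe1, the mitochondrial cochaperonin, rose 1.64-fold (adjusted p = 0.00054). The remaining large rises by estimated log2 change were in Mmp3 and Mmp13, matrix metalloproteinases (at least 2.98- and 1.14-fold, adjusted p = 0.008 and 0.04), Slc13a5, a citrate importer (4.23-fold), Slc5a3, an inositol transporter (3.75-fold), and Acp3, a phosphatase (3.75-fold). The ranks of Mmp3 and Mmp13 here, and those of Pbsn, Odad4 and Thrb among the falls, are not established, since their dimmer group was not above the nonspecific probes. Besides Phgdh and Psat1 the 10 largest falls by estimate comprised Pbsn (log2 -1.80 ± 0.37, with neither group above the nonspecific probes), Odad4 (at least 2.45-fold), Otub2 (2.89-fold) and Thrb, the thyroid hormone receptor beta (at least 1.52-fold). They also comprised Alkbh2 (2.40-fold), Dixdc1 (2.35-fold), the Wnt receptor gene Fzd1 (2.33-fold) and St6galnac4 (2.29-fold), with adjusted p between 1e-04 for Otub2 and 0.023 for Dixdc1.

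The hypoxia, neutrophil, p53 and sterol lists passed with the preset correlation and not with an estimated one. Hypoxia response genes had a median of 0.25 with 0 of 22 past the threshold and 2 adjusted over the list alone (adjusted p = 6.1e-04; adjusted p = 0.69 with an estimated correlation). Ndrg1 stood at 1.74-fold (adjusted p = 0.076). Neutrophil markers had a median of 0.55 with 0 of 9 past the threshold either way (adjusted p = 0.0079; adjusted p = 0.69 with an estimated correlation). S100a8 was at 2.30-fold (adjusted p = 0.44). In control sham arrays the mean of the neutrophil list (4.12) lay under that of the brightest nonspecific probe (4.51). For p53 targets 2 of 13 rose, also adjusted over the list alone, with a median of 0.28 (adjusted p = 0.008; adjusted p = 0.32 with an estimated correlation). They were Ccng1, cyclin G1, at 2.10-fold (adjusted p = 7.2e-05) and Mdm2, the p53 ubiquitin ligase, at 1.52-fold (adjusted p = 0.022). Sterol genes had a median of -0.25 with 0 of 21 past the threshold either way (adjusted p = 0.006; adjusted p = 0.91 with an estimated correlation). Among lists that did not pass, Fosl1, an AP-1 subunit, passed upward (log2 1.08 ± 0.26, adjusted p = 0.034) with neither group above the nonspecific probes, and Me1 and Asns fell 2.02- and 1.93-fold (adjusted p = 0.004 and 0.023). Cytokine genes had a median of -0.06 with 0 of 25 past the threshold in limma and adjusted over the list alone (adjusted p of the list 0.90). Duct and matrix lists had medians of 0.12 and -0.01 (adjusted p = 0.38 and 1). In the fit of these 2 groups alone 11 genes passed in place of 115, and leaving out 1 array gave between 50 genes (without control H/R replicate 4) and 190 (without control H/R replicate 3).

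The question of the same insult in cirrhotic livers was addressed by ligated H/R against ligated sham rats. Il1b, the pro-inflammatory cytokine interleukin 1 beta, rose 4.86-fold (log2 2.28 ± 0.46, adjusted p = 0.023), with the 6 H/R arrays at 10.31 to 11.40 and the 5 sham arrays at 6.62 to 9.88. Hspb1 rose 5.67-fold (log2 2.50 ± 0.44, adjusted p = 0.0086) and Hsph1, a large heat shock protein, 2.88-fold (log2 1.53 ± 0.27, adjusted p = 0.0086). Penk, which encodes the enkephalin precursor, rose 4.07-fold (log2 2.02 ± 0.34, adjusted p = 0.0086). The number past the threshold was 18, with 16 higher and 2 lower, of which 8 rose and 1 fell at least 2-fold.

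The other named rises were in Pira2, an immunoglobulin-like receptor of myeloid cells (2.62-fold, adjusted p = 0.023), Bcl2a1, an anti-apoptotic BCL2 relative (2.58-fold, adjusted p = 0.013), and Procr, the protein C receptor of endothelium (2.37-fold, adjusted p = 0.03). Rises were also seen in Gda, guanine deaminase (2.19-fold, adjusted p = 0.01), Dnajb9 (1.86-fold, adjusted p = 0.023) and Pcsk5, a proprotein convertase (1.83-fold, adjusted p = 0.032). Both falls were in Celf5, an RNA-binding protein (at least 2.23-fold, adjusted p = 0.0086), and Scrn2 (1.57-fold, adjusted p = 0.047). The call of Pira2 was lost in 11 of 21 alternatives, among them the fit of these 2 groups alone (adjusted p = 0.18), the ending of the sample number as a block (adjusted p = 0.33) and the mean of its probe sets (log2 0.29, adjusted p = 0.61).

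Among 25 cytokine, chemokine and adhesion genes 24 had positive changes, and 1 rose over all genes against 18 adjusted over the list alone. The median was 1.36, camera gave an adjusted p of 1.8e-25, and the list held with an estimated correlation (adjusted p = 0.028). Il1a stood at 6.63-fold (adjusted p = 0.056), the monocyte chemokine gene Ccl7 at 4.57-fold (adjusted p = 0.051) and the neutrophil chemokine gene Cxcl1 at 3.46-fold (adjusted p = 0.081), just short of the threshold over all genes. Neutrophil markers had a median of 0.73 with 0 of 9 past the threshold and 6 adjusted over the list alone (adjusted p = 1.9e-07; adjusted p = 0.085 with an estimated correlation). S100a8 was at 3.62-fold (adjusted p = 0.27). Macrophage markers had a median of 0.24 with 0 of 16 past the threshold either way (adjusted p = 7.6e-05; adjusted p = 0.22 with an estimated correlation). Lymphocyte markers had a median of 0.22 with 1 of 18 adjusted over the list alone (adjusted p = 0.0012; adjusted p = 0.26 with an estimated correlation). Red cell markers had a median of 0.27 with 0 of 8 (adjusted p = 0.002; adjusted p = 0.12 with an estimated correlation).

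Heat shock genes rose in 3 of 14 cases (8 adjusted over the list alone), with a median of 0.50 and an adjusted p of 4.3e-13 (adjusted p = 0.085 with an estimated correlation). The hypoxia list had positive changes in all 22 genes, 0 of them past the threshold and 4 adjusted over the list alone (median 0.37, adjusted p = 1.2e-10; adjusted p = 0.085 with an estimated correlation). Adm, adrenomedullin, was at 2.57-fold (adjusted p = 0.22). Of the 21 unfolded protein genes only Dnajb9 rose, also adjusted over the list alone (median 0.30, adjusted p = 2.5e-06; adjusted p = 0.17 with an estimated correlation). With 0 genes past the threshold over all genes, 3 further lists passed upward. They were immediate early genes (median 0.44, adjusted p = 1.1e-05; adjusted p = 0.26 with an estimated correlation), acute phase proteins (median 0.10, 4 adjusted over the list alone, adjusted p = 4.7e-04; adjusted p = 0.40 with an estimated correlation) and NRF2 targets (median 0.27, 4 higher and 2 lower adjusted over the list alone, adjusted p = 0.0088; adjusted p = 0.12 with an estimated correlation). Sterol (median -0.13, adjusted p = 0.0039; adjusted p = 0.51 with an estimated correlation), hepatocyte (median -0.10, adjusted p = 0.049; adjusted p = 0.65 with an estimated correlation) and cell cycle lists (median -0.19, adjusted p = 0.049; adjusted p = 0.65 with an estimated correlation) passed downward. In the fit of these 2 groups alone 3 genes passed, and with the ending of the sample number as a block, whose meaning the labels do not state, 4 passed, both without Il1b (log2 2.28 and 2.40, adjusted p = 0.15 and 0.29). The block also turned the medians of acute phase proteins to -0.13, of duct markers to 0.42 and of P450 genes to -0.74, and Il1b lost its call in 10 of 21 alternatives in all. In this block fit only arrays whose ending occurs in both arms inform the H/R effect. Several arrays have an ending found in 1 arm only. For 1 shared ending, ligated sham replicate 3 is the only sham array. Leaving out 1 array gave between 2 genes (without ligated H/R replicate 1) and 45 (without ligated sham replicate 3), and the cell cycle median turned to 0.01 without ligated H/R replicate 3.

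Whether H/R acted differently in ligated and control livers was tested as the difference of both effects. Clec4m, a C-type lectin of sinusoidal endothelium, was the 1 gene of 13438 that passed, with a difference of -1.46 ± 0.24 (adjusted p = 0.013), and 734 genes had an unadjusted p under 0.05 against 672 by chance. Its mean signal was 5.25 in control H/R and 3.78 in control sham arrays, and 2.74 and 2.72 in ligated H/R and ligated sham arrays. The nonspecific probes reached 4.51 in control sham, 4.00 in ligated H/R and 3.64 in ligated sham arrays on average, so of these groups only control H/R lay above them and no response of Clec4m could be read in ligated livers. The 5 genes of next smallest p did not pass: Rcan2 (-1.61 ± 0.32), Dnaja4 (-1.80 ± 0.37), Odad4 (1.88 ± 0.40) and Foxp2 (0.94 ± 0.20), each at adjusted p = 0.11, and Phgdh (1.81 ± 0.40, adjusted p = 0.13). Foxp2 was not above the nonspecific probes in any of the 4 groups, and Odad4 was not above them in control H/R arrays. The cytokine list differed at a median of 1.74 with 0 of 25 genes past the threshold and 15 adjusted over the list alone, an adjusted p of 3.2e-19 with the preset and adjusted p = 0.098 with an estimated correlation. For Il1b the difference was 2.25 ± 0.65 (adjusted p = 0.61), and for Hspb1 it was -1.79 ± 0.62 (adjusted p = 0.72). The unfolded protein list (median 0.35, 2 genes adjusted over the list alone, adjusted p = 3.8e-06; adjusted p = 0.36 with an estimated correlation) and the heat shock list (median -0.21, 3 genes lower adjusted over the list alone, adjusted p = 0.0042; adjusted p = 0.84 with an estimated correlation) also passed with the preset correlation. So did red cell markers (median 0.27, adjusted p = 0.013; adjusted p = 0.36 with an estimated correlation) and, each at adjusted p = 0.036 and at adjusted p = 0.84 with an estimated correlation, immediate early (median 0.30), acute phase (0.10) and P450 genes (0.43). In all 4 groups the mean of the red cell list lay under that of the brightest nonspecific probe. Clec4m did not pass in the fit of the 4 groups alone (adjusted p = 0.13), with arrays centred on their medians (0.062), or without control sham replicate 1 (0.056), ligated sham replicate 3 (0.052) or ligated sham replicate 4 (0.055), and over all alternatives its difference was between -1.60 and -1.34.

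Across genes, which are not independent replicates, the H/R effects of control and ligated livers had a Pearson r of 0.34 (Spearman 0.30, jackknife SE over arrays 0.12). Of the 115 genes that passed in control livers 95 (82.6%) had a change of the same sign in ligated livers. The 3 genes that passed in both rose in both, against 0.154 expected from independent lists. Both comparisons use the same estimate of spread per gene, so 0.154 may be too low. For control and simvastatin-treated livers r was 0.15 (Spearman 0.14, SE 0.10), and for ligated livers with and without simvastatin 0.21 (Spearman 0.24, SE 0.24).

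**Figure D2:**
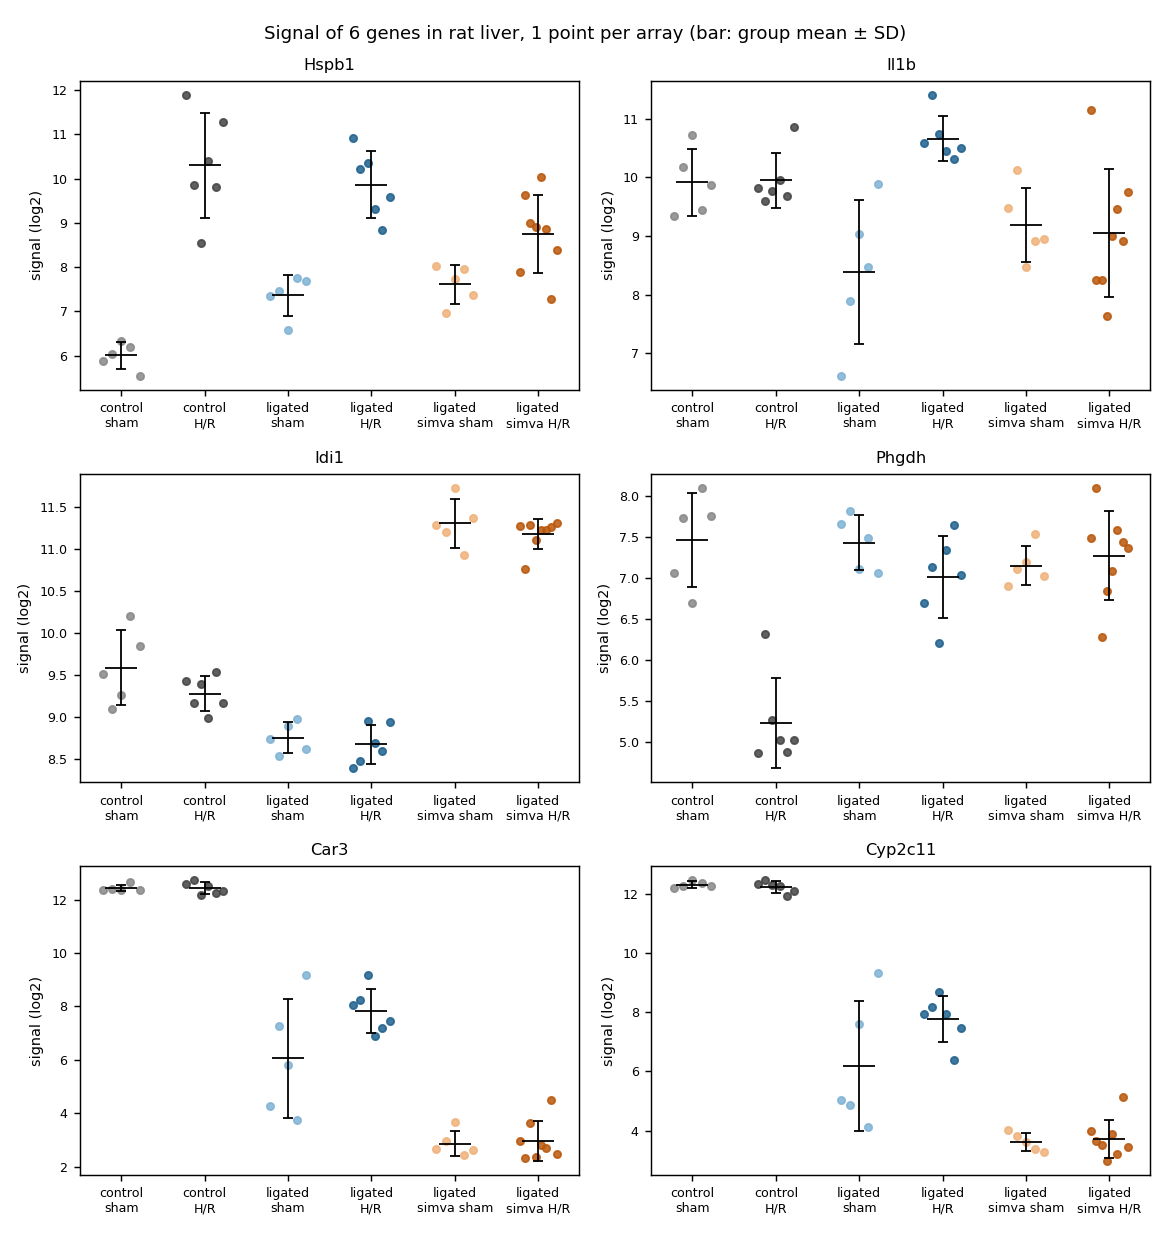
Log2 signal (vertical axes) of 6 genes in the 6 groups (horizontal axis); points are arrays, and the bar with whiskers is the group mean ± SD. Hspb1 means are 6.01 and 10.30 in control sham and control H/R arrays, Il1b means 8.38 and 10.66 in ligated sham and ligated H/R arrays, Idi1 means 8.75 and 11.30 in ligated sham and simvastatin sham arrays, and Car3 and Cyp2c11 means 12.43 and 12.31 in control sham against 2.86 and 3.61 in simvastatin sham arrays. The remaining panel shows Phgdh.

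Simvastatin was examined first without hemorrhage, in simvastatin sham against ligated sham rats. Sterol synthesis genes rose as a group. Idi1, an isomerase of the mevalonate path, rose 5.85-fold (log2 2.55 ± 0.16, adjusted p = 1.1e-12), and Acat2, the thiolase at its start, 6.18-fold (log2 2.63 ± 0.19, adjusted p = 2.8e-11). Mvd, mevalonate diphosphate decarboxylase, rose 6.39-fold (log2 2.68 ± 0.26, adjusted p = 1.1e-08), and Cyp51, lanosterol demethylase, 3.25-fold (log2 1.70 ± 0.16, adjusted p = 4.9e-09). All 21 measured sterol genes had positive changes, and 17 rose over all genes and 20 adjusted over the list alone. The median was 1.32, with an adjusted p of 6.2e-64 and adjusted p = 2.1e-05 with an estimated correlation. Car3 fell at least 6.94-fold (log2 -3.20 ± 0.59, adjusted p = 0.0019) and Cyp2c11 6.00-fold (log2 -2.59 ± 0.56, adjusted p = 0.013). Altogether 105 genes passed, 85 higher and 20 lower, of which 28 rose and 4 fell at least 2-fold.

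Outside the sterol list the largest rises were in Nfe2, a transcription factor of blood cell precursors (at least 3.59-fold, adjusted p = 1.2e-07), Aacs, which activates acetoacetate for lipid synthesis (4.58-fold, adjusted p = 8.2e-10), Elovl6 (3.70-fold, adjusted p = 0.00099) and Cd200r1l, a relative of the CD200 receptor (3.48-fold, adjusted p = 0.034). Within it Hsd17b7 and Msmo1, enzymes of late sterol synthesis, rose 5.49- and 3.74-fold. Cyp39a1, an oxysterol hydroxylase, fell 2.42-fold (adjusted p = 0.0072), and Anp32a, Eml2, Raph1, Lpgat1, Nefh, Csnk2a1 and Ccdc96 fell between 1.67- and 2.11-fold. Klf2, an endothelial transcription factor induced by statins in culture, was at log2 0.10 ± 0.28 (adjusted p = 0.93), and Nos3, endothelial nitric oxide synthase, at -0.20 ± 0.22 (adjusted p = 0.79). Nos3 was not above the nonspecific probes in either group, so its value does not tell whether it changed.

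Macrophage markers had a median of 0.30 with 1 of 16 past the threshold and 5 adjusted over the list alone (adjusted p = 3e-04; adjusted p = 0.91 with an estimated correlation). The 1 was Spic, a transcription factor of iron-recycling macrophages, at 2.12-fold (adjusted p = 0.013). The hepatocyte list (median -0.15, 0 of 20 past the threshold either way, adjusted p = 0.0019; adjusted p = 0.91 with an estimated correlation) and the cell cycle list (median -0.30, 0 of 25 either way, adjusted p = 0.0084; adjusted p = 0.91 with an estimated correlation) also passed with the preset correlation. Cytokine genes had a median of 0.24 (adjusted p = 0.25). The difference of hybridisation controls that separated control from ligated arrays differed here too, at 2.55 ± 0.12 (SD, 11 arrays) in untreated ligated and 2.81 ± 0.11 (SD, 13 arrays) in simvastatin arrays (permutation test, p = 7e-05). The 5S ribosomal RNA signal was at 6.68 ± 0.72 and 5.34 ± 0.53 (permutation test, p = 1e-04). In simvastatin sham replicate 1 the GAPDH signal at the 3' end exceeded that at the 5' end by 2.20, against 0.00 to 0.34 in the other arrays. Centring arrays on their medians gave 47 genes higher and 28 lower, and the fit of these 2 groups alone gave 22 genes, without Car3 (adjusted p = 0.28) and Cyp2c11 (adjusted p = 0.40) at unchanged folds. With the difference of hybridisation controls as a covariate, chosen after seeing the data, 48 passed, without Car3, whose change went from -3.20 ± 0.59 to -2.76 ± 0.83 (adjusted p = 0.18), and Cyp2c11, which went from -2.59 ± 0.56 to -1.52 ± 0.71 (adjusted p = 0.43). Without simvastatin sham replicate 1 the count was 168, and without ligated sham replicate 1 it was 66.

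**Figure D3:**
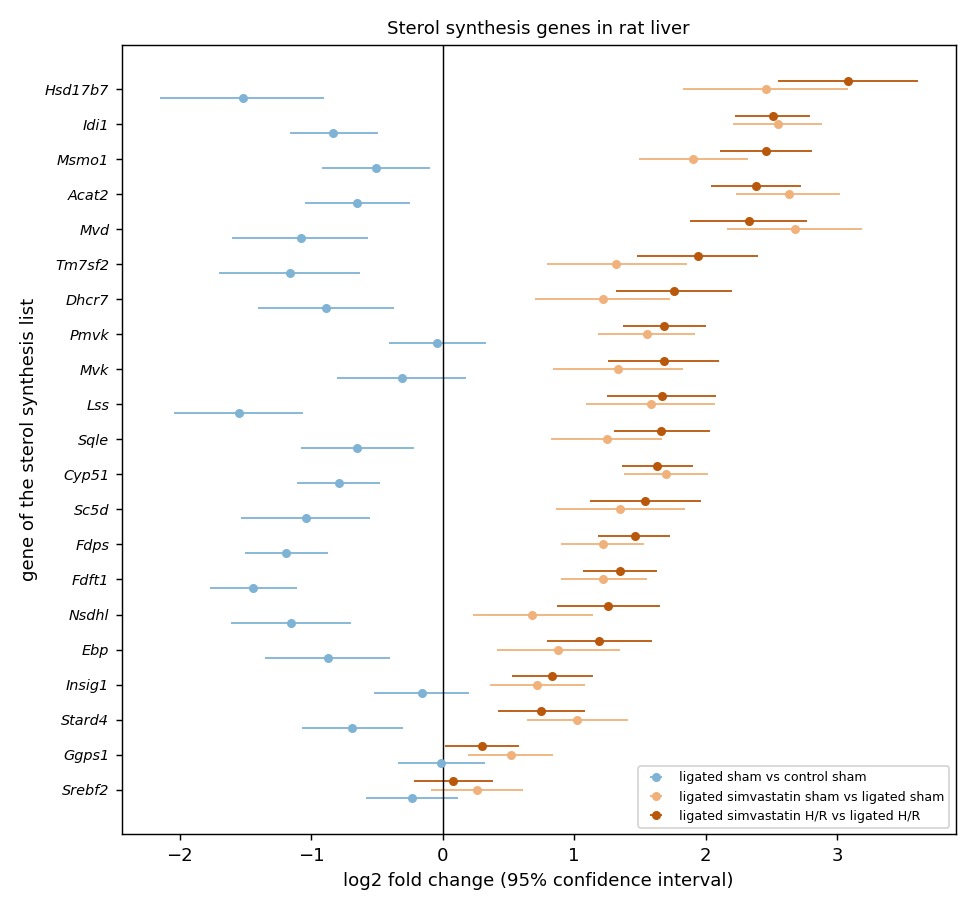
Log2 fold change with 95% confidence interval (horizontal axis) of the 21 sterol genes (vertical axis) for ligation in sham rats, simvastatin in sham rats and simvastatin in H/R rats. The medians are -0.83 for ligation, 1.32 for simvastatin in sham rats and 1.66 for simvastatin in H/R rats.

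The effect of simvastatin in animals that underwent H/R was read from simvastatin H/R against ligated H/R rats. Sterol genes again led the rises: Hsd17b7 rose 8.47-fold (log2 3.08 ± 0.26, adjusted p = 4.3e-10), Idi1 5.68-fold (log2 2.51 ± 0.14, adjusted p = 1.6e-14) and Msmo1 5.49-fold (log2 2.46 ± 0.17, adjusted p = 4.4e-12). Car3 fell at least 23-fold (log2 -4.87 ± 0.50, adjusted p = 3.4e-08) and Cyp2c11 16.5-fold (log2 -4.04 ± 0.48, adjusted p = 7.1e-07). The cytokine genes Il1a and Il1b fell 5.12- and 3.06-fold (log2 -2.36 ± 0.55 and -1.61 ± 0.41, adjusted p = 0.02 and 0.038), and the call of Il1b was lost in 14 of 24 alternatives (log2 -1.91 to -1.32 over all of them). Birc5, the mitotic protein survivin, fell 2.09-fold (log2 -1.07 ± 0.19, adjusted p = 0.00099). In all 182 genes passed, 114 higher and 68 lower, of which 28 rose and 23 fell at least 2-fold.

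Of the 21 sterol genes 19 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 1.66, an adjusted p of 1.4e-74 and adjusted p = 5.2e-06 with an estimated correlation. Other rises were in Acat2, Mvd, Tm7sf2 and Dhcr7 of the same path (3.39- to 5.21-fold), in Aacs (3.77-fold), in Acss2, acetyl-CoA synthetase (3.52-fold), and in Elovl6 (3.71-fold). In the lipogenesis list Elovl6 and Acly, ATP citrate lyase (1.99-fold, adjusted p = 0.018), were 2 of 14 to rise, against 3 adjusted over the list alone (adjusted p of the list 0.053). The remaining large falls were in Obp3 (at least 4.12-fold), Slpi, a secreted protease inhibitor (3.99-fold), Serpina6, the corticosteroid-binding globulin (3.34-fold), Ust5r, an organic anion transporter relative (3.22-fold), Dusp2, a MAP kinase phosphatase of immune cells (2.76-fold), and G0s2, an inhibitor of triglyceride lipase (2.70-fold).

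Cell cycle genes had negative changes in all 25 cases, 3 falling over all genes and 19 adjusted over the list alone (median -0.70, adjusted p = 2.1e-14; adjusted p = 0.26 with an estimated correlation). With Birc5 the falls were in Cdc20, an activator of the anaphase-promoting complex (1.58-fold, adjusted p = 0.019), and Top2a, topoisomerase II alpha (2.34-fold, adjusted p = 0.039). All 25 cytokine genes were likewise lower, 2 past the threshold and 9 adjusted over the list alone (median -0.72, adjusted p = 1.3e-10; adjusted p = 0.26 with an estimated correlation). Neutrophil markers were lower in 9 of 9 cases, 0 past the threshold and 3 adjusted over the list alone (median -0.73, adjusted p = 8.4e-05; adjusted p = 0.30 with an estimated correlation). In the matrix list Col1a1, type I collagen (1.89-fold, adjusted p = 0.02), and Loxl2, a lysyl oxidase (1.78-fold, adjusted p = 0.028), were the 2 of 27 to fall, against 7 lower and 1 higher adjusted over the list alone (median -0.23, adjusted p = 0.0039; adjusted p = 0.45 with an estimated correlation). Heat shock genes had 1 fall of 14, in Hsph1 at 1.96-fold (adjusted p = 0.032), and 4 adjusted over the list alone (median -0.28, adjusted p = 7.4e-04; adjusted p = 0.45 with an estimated correlation).

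The next 6 lists passed with the preset correlation and had 0 genes past the threshold over all genes or adjusted over the list alone. Lower were the unfolded protein list (median -0.16, adjusted p = 7.4e-04; adjusted p = 0.45 with an estimated correlation), lymphocyte markers (median -0.20, adjusted p = 8.1e-04; adjusted p = 0.35 with an estimated correlation) and red cell markers (median -0.18, adjusted p = 0.028; adjusted p = 0.35 with an estimated correlation). So were immediate early genes (median -0.16) and the hypoxia list (median -0.13), both at adjusted p = 0.042 and at adjusted p = 0.63 with an estimated correlation. In ligated H/R arrays the means of the lymphocyte (3.87) and red cell lists (3.56) lay under that of the brightest nonspecific probe (4.00). Fatty acid oxidation was higher (median 0.29, adjusted p = 8.4e-04; adjusted p = 0.45 with an estimated correlation). Tsc22d3, a glucocorticoid target, rose 1.91-fold (adjusted p = 0.049), Sesn1, a p53 target, 1.84-fold (adjusted p = 0.046), and Gsta1, a glutathione transferase, 1.40-fold (adjusted p = 0.013). Klf2 was at log2 0.80 ± 0.24 (adjusted p = 0.085) and Nos3 at -0.02 ± 0.19 (adjusted p = 0.98), with neither group above the nonspecific probes for Nos3.

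Of the genes past the threshold in the sham and in the H/R comparison of simvastatin, which share no arrays, 49 were the same, 43 higher in both and 5 lower in both, where independent lists would share 1.42. Both comparisons use the same estimate of spread per gene, so the lists are not independent and 1.42 may be too low. Centring arrays on their medians gave 90 genes higher and 98 lower. With the difference of hybridisation controls as a covariate, chosen after seeing the data, 35 genes passed, with Car3 (log2 -4.33 ± 0.83) and without Cyp2c11 (-2.72 ± 0.70, adjusted p = 0.16), Il1a (-1.60 ± 0.88, adjusted p = 0.58) and Il1b (-1.78 ± 0.65, adjusted p = 0.38). That fit used ligated arrays only, and for the genes that lost their call the errors widened. The changes of Cyp2c11 (from -4.04 ± 0.48) and Il1a (from -2.36 ± 0.55) also became smaller, while that of Il1b (from -1.61 ± 0.41) did not. The hypoxia and P450 medians turned to 0.09 and 0.61, while leaving out 1 array gave between 100 genes (without ligated H/R replicate 1) and 342 (without simvastatin H/R replicate 3).

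The effect of H/R in simvastatin-treated livers was compared between simvastatin H/R and simvastatin sham rats. In limma 0 of 13438 genes passed, with 725 at an unadjusted p under 0.05 against 672 by chance, and limma with array weights gave 6. The 5 genes of smallest p were Nat8f5 (log2 -0.66 ± 0.14), the protease inhibitor gene A2m (1.17 ± 0.26), Pimreg (-1.04 ± 0.23) and Cyp3a9 (1.85 ± 0.42), each at adjusted p = 0.34, and Ncaph, a condensin subunit (-0.82 ± 0.19, adjusted p = 0.37). Nat8f5 and Pimreg were not above the nonspecific probes in simvastatin H/R arrays, so their folds are bounds of at least 1.04 and 1.47. Hspa1a stood at 1.33 ± 0.47 (adjusted p = 0.83) and Hspb1 at 1.14 ± 0.41 (adjusted p = 0.85).

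No list held with an estimated correlation in this comparison. Cell cycle genes had a median of -0.76, with 0 of 25 past the threshold and 15 adjusted over the list alone (adjusted p = 3.1e-16; adjusted p = 0.30 with an estimated correlation), Aurkb, a mitotic kinase, standing at -0.91 ± 0.25 (adjusted p = 0.60). Upward with the preset correlation went immediate early genes (median 0.31, adjusted p = 2.8e-06), acute phase proteins (0.16, 1 gene adjusted over the list alone, 3.4e-06), the hypoxia list (0.16, 9e-05), red cell markers (0.12, 0.008) and NRF2 targets (0.13, 0.040), each at adjusted p = 0.30 with an estimated correlation. The same held for the unfolded protein list (0.16, 4.1e-04; adjusted p = 0.32 with an estimated correlation), for hepatocyte genes (0.07, 6.7e-04) and heat shock genes (0.21, 0.004), both at adjusted p = 0.45 with an estimated correlation. It held too for cytokines (0.27, 0.0067; adjusted p = 0.51 with an estimated correlation), P450 genes (0.11, 1 gene adjusted over the list alone, 0.033; adjusted p = 0.47 with an estimated correlation) and gluconeogenesis (0.10, 0.033; adjusted p = 0.42 with an estimated correlation). Lymphocyte markers (-0.21, 6.7e-04; adjusted p = 0.30 with an estimated correlation), macrophage markers (-0.16, 1 gene lower adjusted over the list alone, 0.0054; adjusted p = 0.43 with an estimated correlation) and the matrix list (-0.17, 1 gene lower adjusted over the list alone, 0.034; adjusted p = 0.48 with an estimated correlation) went down. The red cell list had means of 3.16 in simvastatin sham and 3.32 in simvastatin H/R arrays, where the brightest nonspecific probe averaged 3.26 and 3.32.

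The difference between this H/R effect and that in untreated ligated livers was tested directly. Pira2 was the 1 gene that passed, with a difference of -2.44 ± 0.38 (adjusted p = 0.0038), and 654 genes had an unadjusted p under 0.05 against 672 by chance. Its mean rose from 4.18 in ligated sham to 5.57 in ligated H/R arrays and stood at 5.56 in simvastatin sham and 4.50 in simvastatin H/R arrays. With its probe sets averaged the difference was -0.57 (adjusted p = 0.88), with the ending of the sample number as a block -2.39 (adjusted p = 0.17), and with the duct and matrix mean or the difference of hybridisation controls as a covariate -2.47 in both (adjusted p = 0.051 and 0.058). Dock9 (0.86 ± 0.16, adjusted p = 0.057), the protease inhibitor gene Slpi (-3.04 ± 0.68, adjusted p = 0.37), and Cd5l, a secreted macrophage protein (-2.60 ± 0.62), Mnda (-1.38 ± 0.35) and Me2 (-1.08 ± 0.28), the last 3 at adjusted p = 0.53, did not pass.

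Cytokine genes had a median difference of -1.22, with 0 of 25 past the threshold and 1 adjusted over the list alone (adjusted p = 4.3e-13; adjusted p = 0.11 with an estimated correlation). Il1b stood at -2.42 ± 0.63 (adjusted p = 0.53). Macrophage markers (-0.43, 5 adjusted over the list alone, adjusted p = 8.6e-08), neutrophil markers (-0.85, 5 adjusted over the list alone, adjusted p = 8.6e-08) and lymphocyte markers (-0.46, 0 adjusted over the list alone, adjusted p = 9.5e-08) differed in the same direction, each at adjusted p = 0.11 with an estimated correlation. S100a8, a neutrophil alarmin, stood at -2.77 ± 0.86 (adjusted p = 0.61). The lymphocyte list had means of 3.61 in ligated sham and 3.87 in ligated H/R arrays. Both lay under the average of the brightest nonspecific probe there (3.64 and 4.00). Heat shock (-0.37, 2 lower adjusted over the list alone, adjusted p = 9.8e-06; adjusted p = 0.42 with an estimated correlation), cell cycle (-0.40, adjusted p = 4.6e-05; adjusted p = 0.49 with an estimated correlation), matrix (-0.34, adjusted p = 0.018; adjusted p = 0.49 with an estimated correlation) and hypoxia lists (-0.19, adjusted p = 0.011; adjusted p = 0.50 with an estimated correlation) were also lower. Hepatocyte (0.22, adjusted p = 1.7e-05; adjusted p = 0.48 with an estimated correlation), bile acid (0.18, adjusted p = 0.013), lipogenesis (0.14, adjusted p = 0.026), both at adjusted p = 0.49 with an estimated correlation, and gluconeogenesis lists (0.20, adjusted p = 0.027; adjusted p = 0.48 with an estimated correlation) were higher. Klf2 differed by 0.69 ± 0.37 (adjusted p = 0.99) and Nos3 by 0.18 ± 0.29 (adjusted p = 1), with none of the ligated groups above the nonspecific probes for Nos3.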

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

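All tests of explanations in these paragraphs, the counts from regrouped arrays included, were chosen after the result they address had been seen. Values of single arrays below are the gap to the nearest array divided by the range of the group, which Dixon's test compares with a 95% limit, and chance alone passes about 1 in 20 groups.

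Genes outside the sterol list moved together with simvastatin, some of them, such as Aacs and Elovl6, also genes of lipid synthesis. Of the genes past the threshold in both the sham and the H/R comparison in the same direction, 31 lay outside the sterol list, 26 of them higher, among them Nfe2 (2.74 and 1.37), Elovl6 (1.89 and 1.89), Car3 (-3.20 and -4.87, at background in the treated groups) and Cyp2c11 (-2.59 and -4.04). Degraded RNA in simvastatin sham replicate 1 is argued against, since 30 of the 31 still passed in the sham comparison without it, and so is a different extent of ligation damage, since 25 passed in both with the duct and matrix mean as a covariate. An array or hybridisation batch could not be told from the drug: with the difference of hybridisation controls as a covariate 7 of the 31 and 16 of 17 sterol genes still passed in both. That fit used ligated arrays only, so effects of the covariate and of leaving out the control arrays are not separated. The median size of the 31 went from 0.68 to 0.56 while their median standard error went from 0.13 to 0.16. Sterol genes went from 1.65 (SE 0.19) to 1.83 (SE 0.24). The covariate itself differs between treated and untreated arrays, as do the title endings in sham rats. A direct effect of the drug and a batch therefore both stay open.

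Cytokine genes were higher after H/R in ligated and not in control livers. Their mean changed by 1.43 in ligated (exact permutation test, p = 0.0022, 462 arrangements) and by -0.04 in control livers (exact permutation test, p = 0.85). The interaction list had a median of 1.74 that did not hold with an estimated correlation (adjusted p = 0.098). The list mean was 7.49 ± 0.57 (SD) in control sham and 7.45 ± 0.43 in control H/R arrays. In ligated livers it went from 6.30 ± 0.71 in sham to 7.73 ± 0.39 in H/R arrays, so the rise started below the control level and ended near it. A single array is argued against, since the median of the difference was 1.34 at its lowest, without ligated sham replicate 1, and 1.98 at its highest. The cytokine list exceeded the macrophage list by 0.98 (exact permutation test, p = 0.048). More macrophages of unchanged state would raise both lists alike only if both were expressed by macrophages alone. The cytokine list, with its adhesion molecules, was not chosen for that, so this excess does not decide on more macrophages. More neutrophils cannot be told apart, with an excess of 0.42 (exact permutation test, p = 0.35), and newly arrived or activated cells were not tested.

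Simvastatin sham replicate 1 stood apart from all other arrays. Its residual SD was 0.455 against 0.217 to 0.442, its GAPDH 3' minus 5' difference 2.20 against 0.00 to 0.34, and its actin difference 4.30 against 1.41 to 2.34. These values are consistent with degraded RNA, by the GAPDH test at 2.20. An untreated rat labelled as treated is argued against by a sterol list mean of 9.10, where the other treated arrays lie at 8.48 to 9.61 and no untreated ligated array lies above 7.76. Whether damage arose in the tissue or in processing stays open.

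Whether chance can be excluded was read from 100 groupings of the same arrays, and the first count given is that of groupings reaching the real count, the real grouping included. For ligation 1 grouping reached the real count of 6401, and the highest other gave 4472. The same was seen for control H/R (1, real count 115, highest other 64) and for simvastatin in H/R rats (1, real count 182, highest other 28). This argues against chance in these comparisons and does not exclude it, since 1 in 100 is the smallest share that 100 groupings can give. For simvastatin in sham rats few groupings reached the real count (3, real count 105, highest other 122). The same held for ligated H/R, for groupings that ignore the title ending (4, real count 18, highest other 209). In both cases another grouping gave more genes than the real one, so these counts alone do not exclude chance. No adjustment over the comparisons was made. With the title ending as a block 4 genes passed in ligated H/R, 1 of them shared with the 18. That block fit rests only on arrays whose ending occurs in both arms, so how far the title ending contributes to the count of 18 stays open. The grouping with 209 differs in the duct and matrix mean by 0.30, against -0.02 in the real grouping, and a count several times the real one points to a structure of the samples. Whether the duct and matrix difference accounts for it was not tested. For H/R under simvastatin the real count of 0 is reached by all 100 groupings whatever the data, so nothing on chance follows (highest other 7). Chance cannot be excluded for the difference of H/R effects by ligation (12, real count 1, highest other 13) or by simvastatin (5, real count 1, highest other 51).

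Among 150 list means of groups 11 passed Dixon's test (7.3%). Ligated sham replicate 3 passed it for duct markers (0.77), neutrophil markers (0.80) and the unfolded protein list (0.74), and ligated sham replicate 4 for red cell markers (0.72). Ligated H/R replicate 3 passed for the cell cycle (0.70) and replicate 1 for red cell markers (0.82). Simvastatin H/R replicate 1 (0.55) and simvastatin sham replicate 2 (0.78) passed for cytokines, simvastatin H/R replicate 3 for NRF2 targets (0.59), control H/R replicate 6 for duct markers (0.73) and control sham replicate 2 for p53 targets (0.87). Chance gives about 1 in 20 groups.

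Of 24 sets of control probes 3 passed (12.5%, against about 1 in 20 groups by chance), namely GAPDH (0.98) and actin (0.86) in simvastatin sham replicate 1 and actin in control sham replicate 2 (0.73). For single genes 17 of 199 passed (8.5%). Ligated sham replicate 3 was the array for Cd24 (0.72), Dcdc2 (0.91), Eml2 (0.86), Slc22a8 (0.81) and Sncg (0.84), and ligated sham replicate 5 for Obp3 (0.87). In control sham arrays they were Car3 (0.86) and Mmp3 (0.77) in replicate 4 and Hspa1a (0.74) and Sctr (0.92) in replicate 5. In control H/R arrays they were Fzd1 (0.77), Odad4 (0.69) and Phgdh (0.72), and in simvastatin arrays Cyp39a1 (0.71), Cyp2c11 (0.54), Idi1 (0.64) and Il1a (0.53).

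The tests of a difference between H/R effects passed for Clec4m by ligation (-1.46, at background in ligated livers) and for Pira2 by simvastatin (-2.44). By ligation the lists of immediate early genes (0.30), cytokines (1.74), acute phase proteins (0.10), heat shock (-0.21), the unfolded protein response (0.35), red cell markers (0.27) and P450 genes (0.43) passed with the preset correlation. By simvastatin these were hepatocyte (0.22), matrix (-0.34), bile acid (0.18), hypoxia (-0.19), cytokine (-1.22), heat shock (-0.37), macrophage (-0.43), neutrophil (-0.85), lymphocyte (-0.46), cell cycle (-0.40), lipogenesis (0.14) and gluconeogenesis lists (0.20). None of these lists held with an estimated correlation. In untreated ligated arrays the means of the red cell and lymphocyte lists lay under that of the brightest nonspecific probe.

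Of 11980 probe sets with several genes or none listed, control probes left out, 3378 passed after ligation (1586 higher, 1792 lower), 39 in control H/R (17 higher, 22 lower) and 1 in ligated H/R (1 higher). With simvastatin 36 passed in sham (32 higher, 4 lower) and 67 in H/R rats (52 higher, 15 lower), and 0 passed in the other 3 comparisons.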

How the results depend on the processing

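Tests and settings named here as added were chosen after seeing the data; every alternative fixed beforehand was run, the title ending for the 3 comparisons it was fixed for. Over all alternatives 20444 gene values were compared with the reported ones. Of these 19901 kept their status, which includes genes that passed neither as reported nor in the alternative. A further 382 lost their call, 161 gained one and 0 were counted as changing direction. The 382 are no share of the 20444, since only a gene that passed can lose its call. Of 5100 list values 4558 kept their status, 357 lost their call, 177 gained one and 8 were counted as changing direction. The cause of these 8 changes was not tested. Turns of sign without a call were not counted. The sterol median in the difference by ligation, for example, went from 0.03 to -0.03 without control sham replicate 5.

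With only the groups in the comparison 11 genes passed in control H/R, 3 in ligated H/R, 22 with simvastatin in sham rats and 0 in the difference by ligation. Array weights gave 43 in ligated H/R, 397 and 744 with simvastatin in sham and H/R rats, 6 for H/R under simvastatin, all lower, and 3 in the difference by simvastatin, where the acute phase median turned to -0.10. For the difference by ligation the count was 0 above the 30th percentile of mean signal, 2 with quantile normalization again, 0 with centring and 2 with the mean of probe sets. For that by simvastatin it was 2 with trend and robust, 2 above the 30th percentile and 0 with the mean of probe sets. With the title ending as a block 4 genes passed in ligated H/R, 1 of them shared with the 18. There the medians of duct markers (0.42), acute phase (-0.13) and P450 genes (-0.74) turned, as did duct markers in the difference by simvastatin (-0.47). In ligated H/R the block fit rests only on arrays whose ending occurs in both arms.

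Among added settings, the duct and matrix covariate gave 392 with simvastatin in H/R rats and 0 in the difference by simvastatin. Without the 2 arrays of largest residual spread 175 passed with simvastatin in sham and 488 in H/R rats. The hybridisation covariate gave 7 in ligated H/R, 48 and 35 with simvastatin in sham and H/R rats, and 0 in the difference by simvastatin. In H/R rats it turned the hypoxia and P450 medians to 0.09 and 0.61.

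Leaving out 1 array gave 5721 to 6718 genes for ligation, and 0 throughout for H/R under simvastatin. The range for control H/R was 50 to 190, with 56 and 61 without control sham replicates 4 and 5, and 190, 50, 173 and 51 without control H/R replicates 3, 4, 5 and 6. For ligated H/R it was 2 to 45, with 6, 4, 45 and 7 without ligated sham replicates 1, 2, 3 and 4, and 2, 11 and 28 without ligated H/R replicates 1, 4 and 6. The cell cycle median there ran from -0.34 without ligated H/R replicate 1 to 0.01 without replicate 3.

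Simvastatin in sham rats ranged from 66 without ligated sham replicate 1 to 168 without simvastatin sham replicate 1. In H/R rats it ranged from 100 to 342, with 100, 121, 297 and 107 without ligated H/R replicates 1, 2, 3 and 4, and 342 and 114 without simvastatin H/R replicates 3 and 6. The difference by ligation ranged from 0 to 5, with 0 and 5 without control sham replicates 1 and 3, 3 and 5 without control H/R replicates 2 and 3, 0 without ligated sham replicates 3 and 4 each, and 2 without ligated H/R replicate 3. That by simvastatin ranged from 1 to 2, with 2 without ligated H/R replicate 5 or simvastatin sham replicate 4.

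Camera with an estimated correlation lost 77 calls, and fry lost 60 and gained 6. The 77 are no share of the 200 list tests, since only a list that passed can lose its call. Of the lists reported here, only those named in the next sentence held with an estimated correlation. Heat shock in control H/R, cytokines in ligated H/R (median 1.18 to 1.67), sterol genes with simvastatin (1.12 to 1.49 in sham, 1.54 to 1.82 in H/R rats) and duct and matrix genes after ligation passed in all settings. Nonspecific probes had array medians of 1.98 to 2.39 against 3.97 to 4.29 for all probe sets, so changes of genes near that floor may be understated.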

Other observations

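The tests of explanations named here were chosen after the results were seen, and so were the genes grouped by pathway below. No list of amino acid synthesis was fixed or tested as a set. Among single genes looked up in control livers after H/R were Aldh18a1, which opens proline synthesis (log2 -1.09 ± 0.23, adjusted p = 0.015), Pycr3, a proline synthesis reductase (-0.59 ± 0.14, adjusted p = 0.04), and Asns (-0.95 ± 0.21, adjusted p = 0.023), all past the threshold like Phgdh and Psat1. Psph, the last enzyme of serine synthesis (-0.05 ± 0.18, adjusted p = 0.96), and Shmt1 and Shmt2, which turn serine into glycine (-0.33 ± 0.15 and -0.32 ± 0.22, adjusted p = 0.35 and 0.61), did not pass. In the difference of H/R effects by ligation Psat1 (1.25 ± 0.34, adjusted p = 0.56), Asns (1.25 ± 0.30, adjusted p = 0.30) and Aldh18a1 (1.28 ± 0.33, adjusted p = 0.51) did not pass, so a different response of ligated livers was not shown.

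Genes of growth hormone signalling in ligated livers were also looked up one by one, with no set test. Ghr, the growth hormone receptor, fell by 1.57 ± 0.21 log2 (adjusted p = 2e-07), Stat5b, its signal transducer, by 1.59 ± 0.19 (adjusted p = 1.6e-08), and Igf1, its main hepatic target, by 0.66 ± 0.16 (adjusted p = 0.0011), while Socs2, another target, did not pass (-0.58 ± 0.25, adjusted p = 0.059). The male-biased gene Hsd3b5 fell by 2.22 ± 0.48 (adjusted p = 0.00028), as did Car3, Cyp2c11 and Obp3, and Cyp2c12, a female-biased P450, rose by 1.60 ± 0.35 (adjusted p = 0.00035). Female rats among the ligated groups are argued against by the Y-linked gene Uty, at 7.56 at its lowest in ligated arrays and 7.54 to 8.18 in controls.

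Car3 varied widely among untreated ligated livers, from 3.73 to 9.18 in ligated sham and from 6.91 to 9.17 in ligated H/R arrays, and lay between 2.31 and 4.50 in all simvastatin arrays, where its mean was not above the nonspecific probes. Ghr, Stat5b, Igf1 and Socs2 did not pass with simvastatin in sham rats (-0.19, -0.08, -0.36 and -0.99) or in H/R rats (-0.04, -0.04, -0.12 and 0.15). Socs2 in sham rats lay just short of the threshold (-0.99 ± 0.25, adjusted p = 0.056).

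Il1b stood higher in control sham (9.34 to 10.72) than in most ligated sham arrays (6.62 to 9.88), so the values after H/R in ligated livers (10.31 to 11.40) overlap those of controls. On the first principal component, with 63.2% of the variance, ligated sham replicate 3 (-3.1), ligated H/R replicates 3 (4.6) and 4 (6.9) and simvastatin H/R replicate 3 (4.2) were the ligated arrays nearest to the controls.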
